A study of Mus musculus with 6 samples.

How the data were processed

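The samples were 6 Omni-ATAC-seq libraries (a transposase-based assay of open chromatin) of mouse LSK cells. LSK cells are the lineage-negative, Sca-1-positive, Kit-positive fraction of bone marrow that holds haematopoietic stem and progenitor cells. Per the labels, the cells were sorted from C57BL/6 bone marrow, deletion of Fli-1 was induced with 4-hydroxytamoxifen, and the cells were kept for 6 days with E4orf1 vascular niche cells in serum-free medium with the cytokines SCF, Flt3 and TPO as the labels name them. The titles gave 3 Fli-1 knockout libraries (KO 1 to KO 3) and 3 control libraries (WT 1 to WT 3). Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

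Each library came with 1 peak list on build mm10, per the labels. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.4, Bowtie2 2.3.5, Picard 2.21.1, SAMtools 1.9 and MACS2. The MACS2 version, the thresholds and the read shift used for the transposase are not given in the sources used here. Each list was called on 1 library, with no pooling of replicates, as the deposited peak names show. For every summit the deposited lists hold a score, a fold enrichment (a linear ratio of summit coverage to background) and the −log10 of a p-value and of a q-value, all made by the authors' peak caller within that library. These values are the authors' and were used here only to describe, rank and filter peaks inside a list. The lists hold no read counts, so presence or absence of a peak, and ranks inside lists of 1 length, were the quantities compared between libraries.

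Summits sharing a start and end were reduced to 1 peak region, represented by the summit with the highest −log10 p. In each list the authors' fold values lay on an evenly spaced grid, as a ratio of whole coverages plus 1 gives, and the grid spacing gave the background coverage that the caller had used. The p-value recomputed from it as a Poisson tail matched the authors' within 0.01 for 99.89% of the summits checked in KO 3 and 100% in the other lists. The background coverage was used as the measure of depth. The total read number was not used here.

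Peak regions of all 6 lists were merged into 147402 sites wherever they overlapped by at least 1 bp. A WT-only site had a peak in all 3 WT libraries and in no KO library, and a KO-only site the reverse. Lists of different length find weak sites unequally, so the counts were repeated with each list shortened to the 70823 regions of the shortest by the authors' p (equal-length lists). Counts were set beside those from all 10 splits of the libraries into 3 and 3. Group means of values per library were compared by a 2-sided exact permutation test, whose smallest p with 3 against 3 is 0.1.

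The reference was a table of RefSeq gene extents (GRCm38.p6, the mm10 assembly) with 21887 protein-coding genes, without strand, exons or sequence. Transcription start sites were therefore replaced by either end of a gene, within 1 kb, and exons, introns and UTRs could not be separated. A site was assigned to the gene containing its best-ranked summit (the shortest where several did), otherwise to the nearest gene within 100 kb. The planned searches for transcription factor motifs and short sequence words need the genome sequence, and were not run. The same applies to the planned test of exon, intron and intergenic shares, replaced by shares at gene ends and inside genes.

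The 15 gene lists, with 301 entries used of 302 written, were fixed before the data were examined; 1 entry was not a protein-coding gene in the reference. They cover stem cell regulators, megakaryocytes and platelets, erythroid cells, neutrophils, monocytes and macrophages, mast cells with basophils and eosinophils, lymphoid genes, endothelium, niche receptors and adhesion, the cell cycle, AP-1 and immediate early genes, the ETS family, interferon and inflammation, and as controls housekeeping and neuronal genes. WT-only against KO-only sites at a list's genes were compared with those at all other genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the lists. Each list's WT-only minus KO-only count was also placed among those of 10000 random lists matched on the number of assigned sites. Per gene, WT-only sites among its sites in exactly 3 libraries were compared with those of all other genes by a 1-sided Fisher's exact test. Sites are not replicates, so these tests describe the 6 libraries. An odds ratio for a list was carried through the alternatives only with at least 5 group-specific sites, a minimum set after the data were seen.

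Genes were named by a rule fixed beforehand. It took the genes at the 10 best-ranked WT-only and KO-only sites, a site's rank being the worst of its 3 ranks within lists. It also took the 5 genes with the largest difference of WT-only and KO-only sites in each direction, up to 3 genes per described list with the largest absolute difference, and Fli1. Genes named for other reasons are said to be so.

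Alternatives fixed beforehand were a −log10 q of at least 5, equal-length lists, presence defined as cover of 50% of a site, 500 bp windows at summits, the 10000 top peaks or the shortest list in place of the 30000 top peaks, 2.5 kb around gene ends, assignment within 20 kb, autosomes only, each library left out, and a replicate block. Alternatives added after the data were seen were a fold of at least 5, the 30000 top peaks as lists, and the 4 libraries left without the 2 of lowest background coverage, KO 3 and WT 1. Also added then was a ranking of the sites with a peak in all 6 libraries, within each library by the authors' p and, as an alternative, by the authors' fold, carried through the alternatives for 8 lists and 17 genes. So was leaving each gene of a list out in turn, of which the largest p, or the smallest difference in ranks, is given, and the 4 deeper libraries shortened to one length.

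The site rule was tested on simulated data. Coverage was drawn for the 147402 sites from the observed site strengths and each library's background coverage, with 200 sites of middle strength made 2-fold or 4-fold weaker in one group. In equal-length lists, 33 of 50 sites 4-fold higher in WT and 31 of 50 sites 4-fold higher in KO were found as group-specific, against 8 of 50 and 6 of 50 for 2-fold. Of the 147202 unchanged sites, 256 were called WT-only and 243 KO-only in equal-length lists, and 334 and 265 in whole lists. The rule thus misses most 2-fold differences. Draws varied by counting noise only, around a strength per site shared by all libraries. Real libraries may vary more, so the rates of false and missed calls in the data may differ. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.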

Results

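Open chromatin was compared between Fli-1 knockout and wild-type LSK cells after 6 days on vascular niche cells, to ask which accessible regions depend on Fli-1, an ETS-family transcription factor of blood and endothelial cells. Each group held 3 libraries. The lists held 123986, 109250 and 70823 peak regions in KO 1, KO 2 and KO 3, and 93647, 112608 and 113066 in WT 1, WT 2 and WT 3. The background coverage of the caller, used here as the depth, was 3.531, 3.969 and 1.199 reads per position in KO 1, KO 2 and KO 3. It was 2.299, 3.211 and 3.987 in WT 1, WT 2 and WT 3. KO 3 was therefore the shallowest library and WT 1 the next.

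**Figure D1:**
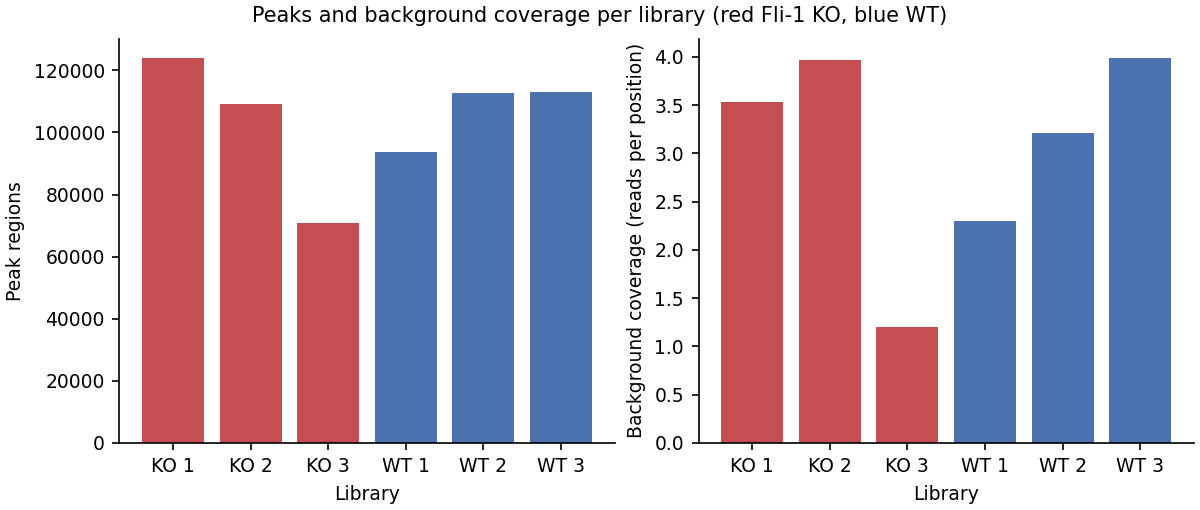
Peak regions (left) and background coverage in reads per position (right) of each library, with Fli-1 KO in red and WT in blue. KO 3 had both the fewest peak regions (70823) and the lowest background coverage (1.199).

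The targeted gene, Fli1, lies on chromosome 9 at 32422204 to 32543432 (mm10). It was overlapped by 25, 22 and 17 peaks in KO 1, KO 2 and KO 3 and by 20, 25 and 23 peaks in WT 1, WT 2 and WT 3. Of the 28 merged sites overlapping the gene, 13 had a peak in all 6 libraries, 0 were WT-only and 1 was KO-only. The KO-only site, at 32484654 to 32485629, had an authors' fold enrichment of 2.43, 3.22 and 4.09 in the 3 KO libraries. The labels do not say which part of the gene was deleted, so peaks over the locus do not check the deletion.

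The overall extent of open chromatin did not separate the groups. Lists held 101353 ± 27447 regions in KO and 106440 ± 11082 in WT (SD, n = 3 each; exact permutation p = 0.8), and covered 81.8 ± 24.1 Mb and 88.1 ± 7.67 Mb (exact permutation p = 0.9). A peak lay within 1 kb of an end of 15075 ± 668 protein-coding genes in KO and 15194 ± 237 in WT (SD, n = 3 each; exact permutation p = 1). Without KO 3 the difference in regions turned to 10178 more per KO library and that in covered length to 7.58 Mb more (exact permutation p = 0.6 and 0.4).

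The strongest peaks of these libraries differed in where they lay, by less as more peaks were taken. Among the 10000 top peaks of each list, 63.1% ± 0.858 in KO and 58.8% ± 2.01 in WT had their summit within 1 kb of a gene end (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), and the groups did not overlap. The planned comparison of the 30000 top peaks gave 34.0% ± 0.278 and 33.3% ± 0.275, a difference of 0.75 percentage points, again without overlap (SD, n = 3 each; exact permutation p = 0.1). Among the 70823 top peaks the shares were 19.1% ± 0.644 and 18.8% ± 0.140 (SD, n = 3 each; exact permutation p = 0.7).

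Of 147402 merged sites, 56836 (38.6%) had a peak in all 6 libraries and 32779 (22.2%) in a single library. WT-only sites numbered 1178 and KO-only sites 473. With lists of equal length there were 1436 WT-only and 937 KO-only sites, of which 152 and 62 overlapped a site of the same kind from the whole lists. The rest fell in merged sites where the full lists also held a peak of the other group. At equal length the terms thus mean a peak within the shortened lists. In equal-length lists the division into KO and WT gave 2373 group-specific sites against 633 in the next of the other 9 splits, and in whole lists 1651 against 2583. The mean Jaccard index between equal-length lists was 0.812 within WT, 0.758 within KO (0.721 and 0.739 for the pairs with KO 3) and 0.748 between the groups. In whole lists it was 0.720, 0.617 and 0.660; KO 1 and KO 2 overlapped at 0.740, and the pairs of KO 3 with them at 0.530 and 0.581. The site counts depend on the libraries used. Without KO 1, KO 2, WT 1, WT 2 or WT 3 the WT-only count was 2846, 2238, 3093, 2125 or 1784, and without KO 3, WT 2 or WT 3 the KO-only count was 4344, 935 or 1047. The 4 deeper libraries alone, without KO 3 and WT 1, gave 3159 WT-only and 4875 KO-only sites.

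**Figure D2:**
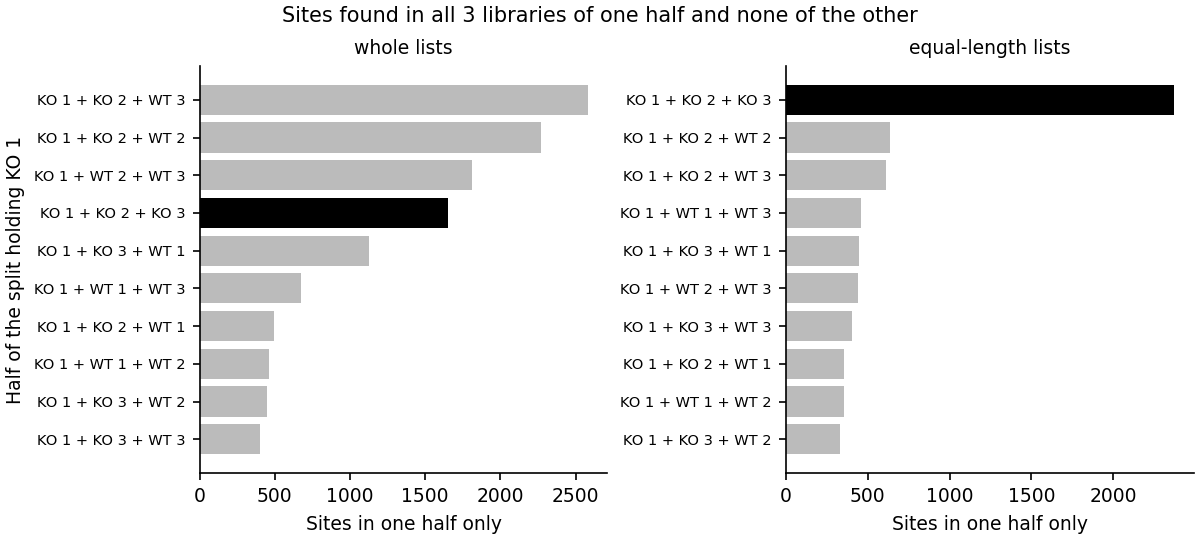
Number of sites with a peak in all 3 libraries on one side and in none on the other (x axis), for each of the 10 splits of the libraries (y axis, named by the side with KO 1), in whole lists (left) and equal-length lists (right). The KO against WT split, in black, gave 1651 sites in whole lists and 2373 in equal-length lists, where the highest other split gave 633.

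The best-ranked WT-only regions lay by Uaca, Irak3 and Stpg4. The region nearest Uaca, a gene linked to apoptosis, at chromosome 9, 60899257 to 60901702, lay 20655 bp outside the gene and had authors' folds of 18.8 to 26.7 in the WT lists. It was the only site among the top 30000 peaks of every WT list with no peak in any KO list, and the reverse case had 0 sites. A region inside Irak3, a negative regulator of Toll-like receptor signalling (chromosome 10, 120190772 to 120192003), had folds of 13.5 to 28.7. One inside Stpg4 (chromosome 17, 87417830 to 87418578) had folds of 12.3 to 16.2. The other best-ranked WT-only regions were assigned to 1700016C15Rik, Arhgef6, Stard3nl, Xdh, Cdh10 and Mical3, and 1 lay over 100 kb from any gene.

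The 10 best-ranked KO-only regions had folds of 6.24 to 13.7; folds depend on a library's background and are not compared between the groups. The first lay inside Cobl, an actin nucleator gene, at chromosome 11, 12444333 to 12444552, with folds of 7.28 to 9.06. Next came a region 11798 bp from Ly6c1, which encodes a surface antigen (chromosome 15, 75060463 to 75060838, folds 7.25 to 9.71). A region 55767 bp from Tox, a regulator of T cell development, followed (chromosome 4, 6630016 to 6630971, folds 7.28 to 13.7). Rgs6, Tmem178b and Trim12a were also assigned such regions, and 4 of the 10 lay over 100 kb from any gene.

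WT-only regions gathered at Cdk6, which encodes a G1 cyclin-dependent kinase. Cdk6 (chromosome 5, 3341004 to 3531008) had 7 WT-only and 0 KO-only sites among its 10 sites found in exactly 3 libraries (1-sided Fisher's exact p = 8.79e-06; adjusted p = 0.0587 over 6680 genes). Etv6, an ETS-family repressor needed for stem cell survival in adult marrow (chromosome 6, 134035700 to 134270158), had 6 WT-only and 0 KO-only of 20 (Fisher's exact p = 0.0110, adjusted p = 1). Ugcg, the glucosylceramide synthase, and Bcl11a, a zinc-finger factor of lymphoid and erythroid development, each had 5 WT-only and 0 KO-only of 6 (Fisher's exact test, adjusted p = 0.120 for both). All 4 such sites of Pttg1, the securin gene, were WT-only (Fisher's exact test, adjusted p = 0.164). Toward KO the largest difference was 2 sites, shared by 11 genes; the 5 with fewest assigned sites, Tex36, Aqp6, Grid2, Galnt15 and Pak1, had 2 KO-only and 0 WT-only sites each. With Fisher's exact test and Benjamini-Hochberg adjustment, 0 genes passed 0.05 in either direction. At an unadjusted p under 0.05 there were 59 genes toward WT and 185 toward KO. These counts do not compare the directions, because the rarer kind of site passes more easily (473 KO-only against 1178 WT-only). A gene whose only site in exactly 3 libraries was KO-only fell under 0.05 (Ly6c1, Fisher's exact p = 0.0377). A gene whose only such site was WT-only did not (Irak3, Fisher's exact p = 0.0997). After adjustment, equal-length lists and the 4 deeper libraries also gave 0 genes. At an unadjusted p under 0.05 there were 18 and 28 in the former and 141 and 62 in the latter. The balance in the latter was the opposite, and there WT-only sites were the rarer kind (3159 against 4875). WT-only and KO-only counts at Cdk6 were 3 and 0 at equal length and 10 and 0 in the 4 deeper libraries, and at Etv6 2 and 0 and 13 and 2.

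**Figure D3:**
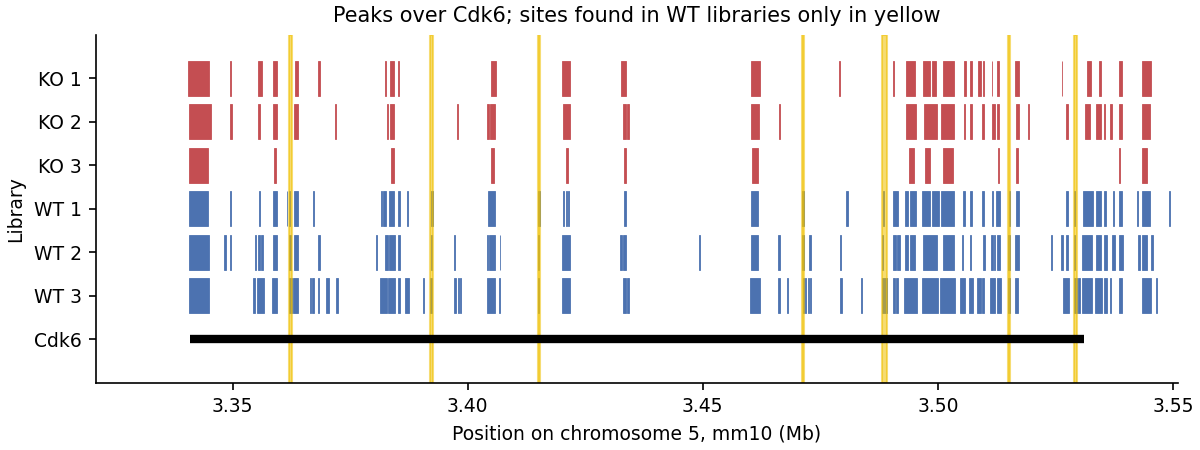
Peaks of each library over Cdk6 and 20 kb on either side (x axis, position on chromosome 5 in Mb, mm10), in red for KO and blue for WT, with the extent of the gene in black. Yellow bands, drawn with a minimum width, mark the 7 sites found in all 3 WT libraries and no KO library.

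Several stem cell and ETS genes were among the carriers of WT-only sites. The stem cell regulators had 14 WT-only and 3 KO-only sites over 30 genes, with 7 genes having more WT-only and 1 more KO-only sites. Etv6 gave 6 of these, Runx1, a core factor of blood formation, gave 2 WT-only and 0 KO-only, and Prdm16, a factor that maintains stem cells, gave 0 WT-only and 2 KO-only. The ETS family had 10 WT-only and 3 KO-only sites, of which Etv6 gave 6 and 0, Erg 2 and 1, Etv1 and Etv5 1 and 0 each, and Fli1, the targeted gene, and Elf2, chosen after its values were seen, 0 and 1 each. The cell cycle list had 11 and 1, of which Cdk6 gave 7, Ccnd1 (cyclin D1) 2 WT-only and Cdkn1a, the p21 inhibitor, the KO-only site. Against all other genes, whose sites were also mostly WT-only, these lists did not pass Fisher's exact test (adjusted p = 1 for each). Adjusted over the list alone, 1 cell cycle gene (Cdk6) and 0 genes of every other list passed in whole lists. At equal length 0 genes passed (lowest adjusted p of the cell cycle list 0.224, Fisher's exact test), and in the 4 deeper libraries Cdk6 and Etv6 did (0.00103 and 0.000351). The WT-only minus KO-only count stood at the 98.9th percentile of matched random lists for the stem cell regulators, the 94.6th for the ETS family and the 99.8th for the cell cycle. At equal length these were the 55.5th, 77.4th and 62.6th, and among the top 30000 peaks the 14.8th, 30.0th and 57.8th.

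Lymphoid genes carried 5 WT-only and 0 KO-only sites in whole lists, at 5 genes that include Cd79a (a B cell receptor chain), Dntt (the terminal transferase of lymphoid progenitors) and Satb1 (a chromatin organiser of lymphoid cells). In equal-length lists there were 11 WT-only and 0 KO-only lymphoid sites at 7 of 22 genes (Fisher's exact p = 0.00479, adjusted p = 0.0719), at the 99.9th percentile of matched random lists. Chosen after their values were seen, Dntt, Satb1, Tcf7 and Flt3 had 2 each at equal length. A KO peak below the cut counts as absent there. Flt3 had 0 WT-only sites in whole lists and 0 in the 4 deeper libraries. Among the 30000 top peaks used as lists there were 4 and 1 lymphoid sites (Fisher's exact p = 0.654). Monocyte and macrophage genes also had 5 WT-only and 0 KO-only sites, 2 of them at F13a1 (coagulation factor XIII) and 1 each at Cx3cr1 and Fcgr3. Among the 30000 top peaks, monocyte genes had 54.3 ± 3.21 in KO and 61.0 ± 2.00 in WT (SD, n = 3 each), with no overlap (exact permutation p = 0.1, adjusted p = 0.75). Erythroid genes had 31.3 ± 2.08 and 35.0 ± 1.73, also with no overlap (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.75). Lymphoid genes had 59.3 ± 3.06 and 66.7 ± 6.66 (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 0.75). Genes of endothelium, the cell type of the niche layer, had 44.7 ± 2.31 and 47.3 ± 2.31 (SD, n = 3 each; exact permutation p = 0.6).

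The remaining lists held few group-specific sites, with adjusted p = 1 by Fisher's exact test for all 15 lists in whole lists. Niche receptors and adhesion genes had 4 WT-only and 2 KO-only sites, with 1 KO-only site at Cxcr4, the receptor that retains stem cells in the marrow, and 1 WT-only site each at Kit and Selplg. Megakaryocyte genes had 2 and 1, with Vwf and Cd9 WT-only and Cavin2 KO-only. Neutrophil genes had 2 and 1, with Ctsg and Cxcr2 WT-only and Csf3r KO-only. Interferon and inflammation genes had 3 and 1, with Il1b and Nfkbia WT-only and Rel KO-only. Endothelial genes had 2 and 1, all at Erg, which the stem cell and ETS lists also hold. Mast cell genes had 1 at Mitf and 1 at Cma1, erythroid genes 1 and 0 at Nfia, and AP-1 genes 1 and 0 at Batf. The control lists had 2 and 0 for housekeeping genes, at Rplp0 and Ywhaz, and 1 and 1 for neuronal genes, at Nefl and Rbfox3.

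Without the shallowest library, KO 3, 4 lists passed an adjusted p of 0.05 toward WT, and the same number did in the 4 deeper libraries. In those 4 libraries lymphoid genes had 17 WT-only and 3 KO-only sites (Fisher's exact test, adjusted p = 0.00125), with 9 genes having more WT-only and 0 more KO-only sites. The cell cycle list had 16 and 5 (Fisher's exact test, adjusted p = 0.00883), the stem cell regulators 28 and 18 (adjusted p = 0.0300) and the ETS family 23 and 15 (adjusted p = 0.0466). The last 3 lost most of their excess without 1 gene. Leaving out Cdk6, the cell cycle list had 6 and 5 (Fisher's exact p = 0.367). Leaving out Etv6, the stem cell regulators had 15 and 16 (Fisher's exact p = 0.363) and the ETS family 10 and 13 (p = 0.832). With each lymphoid gene left out in turn, the largest p came without Mef2c, with 14 and 3 (Fisher's exact p = 0.000629). Shortened to one length, these 4 libraries gave 18 and 2 sites for the cell cycle and 31 and 9 for the ETS family (Fisher's exact test, adjusted p = 0.000677 for both), 15 and 2 for lymphoid genes (0.00410) and 33 and 18 for the stem cell regulators (0.0408). There the cell cycle list had 9 and 2 without Cdk6 (Fisher's exact p = 0.0300, not adjusted), the ETS family 11 and 7 and the stem cell regulators 13 and 16 without Etv6 (Fisher's exact p = 0.244 and 0.855), and lymphoid genes at the largest p 12 and 2, without Ikzf1 (Fisher's exact p = 0.00511). Before shortening, the other pairings of the 4 libraries gave 0 and 1 list past the threshold, against 4 for KO against WT. Other pairings were not counted at one length.

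**Figure D4:**
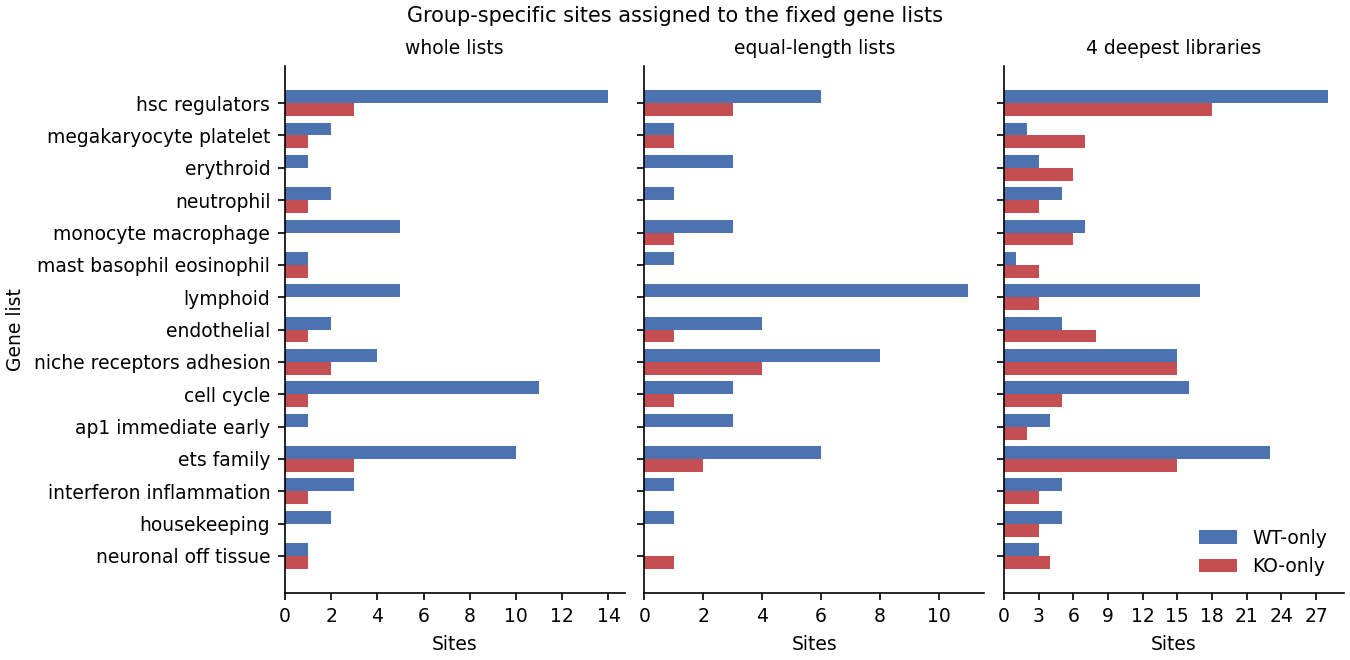
Number of WT-only (blue) and KO-only (red) sites (x axis) assigned to the genes of each fixed list (y axis), in whole lists, in equal-length lists and in the 4 libraries of highest background coverage. Lymphoid genes had 5 WT-only and 0 KO-only sites in whole lists, 11 and 0 in equal-length lists and 17 and 3 in the 4 deeper libraries.

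Group-specific sites in whole lists lay mostly away from gene ends, as did other sites found in exactly 3 libraries. In whole lists 5.18% of WT-only and 4.86% of KO-only sites had their summit within 1 kb of a gene end (95% Wilson intervals 4.05 to 6.60 and 3.26 to 7.19; Fisher's exact p = 0.901), against 4.81% of other sites in exactly 3 libraries (Fisher's exact p = 0.567 and 0.913) and 22.2% of sites found in all 6 libraries. Inside genes lay 56.8% and 54.8% (Fisher's exact p = 0.476). Among the 30000 top peaks used as lists, 4.81% of 770 WT-only and 11.6% of 517 KO-only sites lay at gene ends (Fisher's exact p = 8.16e-06, adjusted p = 9.79e-05). Other sites in exactly 3 of these lists had 12.3%. Only 7 of these WT-only and 0 of these KO-only sites overlapped a site of the same kind at equal length, so here the terms mean a peak among the top 30000, and most such sites are not specific to a group in the longer lists. In the 4 deeper libraries the order was the opposite, 5.29% of WT-only and 4.10% of KO-only sites (Fisher's exact p = 0.0138, adjusted p = 0.0664), while 58.8% and 54.3% lay inside genes (adjusted p = 0.000410). Intervals cover counting error only.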

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

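A fold minimum of 5, the 30000 top peaks as lists, ranking by fold and the removal of KO 3 and WT 1 were chosen after the data were seen, as was the minimum of 5 sites for a list's odds. Group-specific counts move with list length and depth. On simulated data 26 to 33 of 50 sites changed 4-fold were found and 6 to 8 of 50 changed 2-fold, and the lowest fold in a list was 3.18 in KO 3 against 2.41 to 2.73 in the others, so weaker sites are out of reach there. Motif shares, the sequence word screen and exon and intron shares were not run for want of a genome sequence and exon table. Lists with under 5 group-specific sites have no odds ratio here, and a strict presence rule that left 1 site gave no list test. Of 826 settings of named genes, 14 changed sign and 264 moved by over 1.5 times; of 71 settings of list odds, 12 changed sign and 8 came to pass 0.05; of 111 settings of group comparisons, 74 kept their side. All 44 settings of top peaks per list and 199 of 200 of common-site ranks kept direction. Their exact permutation p cannot fall under 0.05 with so few libraries, so their side of that threshold was fixed in advance. The genes ranked there were picked after their values were seen, which favours a kept direction. Unless construction shows it, the cause was not tested.

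With equal-length lists KO-only sites numbered 937, gene ends with a peak differed by 58.3 more in KO, the gene-end share of WT-only minus KO-only sites was -1.10 percentage points, log2 odds of niche receptors were 0.28, and WT-only minus KO-only sites were -1 at Etv5 and Vwf and -2 at Mical3. With −log10 q of at least 5 the gene-end share difference was -0.277 and log2 odds of stem cell regulators -0.99. With a fold of at least 5 KO lists held 842 more peaks and 18 more genes with an end peak, the gene-end share difference was -1.74, and Etv5, Mical3 and Vwf stood at -1. With the 30000 top peaks WT-only sites numbered 770, the gene-end and gene-body share differences were -6.80 and -0.978, log2 odds were -1.06 for stem cell regulators and 0.33 for niche receptors, and Arhgef6, Mical3 and Stard3nl stood at -1. A peak among the top 30000 in one group with no peak in the other left 1 WT-only and 0 KO-only sites, fewer by construction. Where peaks had to cover 50% of a site, log2 odds were -0.0081 for stem cell regulators and 0.82 for niche receptors, and Erg stood at -1. In 500 bp windows Cd9 stood at -1, and with assignment within 20 kb log2 odds of the ETS family were -0.0194.

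Without KO 3 and WT 1 there were 3159 WT-only and 4875 KO-only sites, 4 lists passed, share differences at gene ends and inside genes were 1.18 and 4.59 (Fisher's exact p = 0.0138 and 5.13e-05), log2 odds of niche receptors 0.58, and KO lists held 3781 more peaks, 3.44 Mb more and 128.5 more genes with an end peak. With each library left out in turn, WT-only sites ranged from 1202 to 3093 and KO-only sites from 550 to 4344, higher because fewer libraries must agree. Lists past 0.05 ranged from 0 to 4, the latter without KO 3. The gene-end share difference ranged from -0.364 to 1.54 and that inside genes from 0.132 to 7.05, past 0.05 without KO 2 (7.05), WT 2 (3.94) and WT 3 (4.51). KO minus WT ranged from -16404 to 10178 peaks, -13.9 to 7.58 Mb and -341.7 to 265.3 genes with an end peak, positive only without KO 3. Log2 odds of niche receptors ranged from -0.24 to 0.27. Erg ranged from -1 to 3, Kit from -1 to 2 and Ywhaz from -1 to 3, each at -1 without KO 3. The common-site percentile difference of stem cell regulators ranged from -0.028 to 0.796.

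No pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.0492, 0.0424 and -0.0586 across sites. KO 3 correlated best with WT 1 (0.105), the other shallow library. These correlations cannot show whether same-numbered samples were prepared together. With the replicate block, a sign-flip permutation whose smallest p is 0.25, differences stayed at -5087 regions (exact p = 0.75), -6.29 Mb (p = 1), 0.75 percentage points at gene ends (p = 0.25) and -119 genes (p = 1), and no call could come to pass 0.05.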

Other observations

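The tests of the splits and of depth were chosen after the results were seen, as was the ranking of sites found in every library; the tests on Cdk6 and Etv6 and on the surroundings of Fli1 were written down before their values. Sites with a peak in all 6 libraries were ranked within each library by the authors' p, and the mean percentile of a gene's sites (100 the strongest) was compared. Of 907 genes with at least 10 such sites, 341 (37.6%) had groups that did not overlap, against 10% by chance, with 252 higher in WT and 89 in KO. The single sites without overlap lay near balance (7947 higher in WT and 7805 in KO). Ranks gained and lost within a library cancel over all sites, but this does not fix the number of sites on each side. The split with KO 1, WT 1 and WT 2 on one side gave 1969 sites higher there and 2481 higher on the other. Genes named here were picked after their values were seen. Pag1, an adaptor that restrains Src-family kinases, had the largest median shift toward WT (percentile 38.1 ± 0.165 in KO and 49.7 ± 1.38 in WT, SD, n = 3, over 25 sites), followed by Bcat1 (30.7 ± 2.89 and 39.0 ± 0.816), Tanc1 (35.0 ± 2.98 and 42.1 ± 2.01), Atoh8 (44.7 ± 0.863 and 57.2 ± 1.89) and Tgfbr3 (38.2 ± 2.09 and 45.3 ± 2.87). Runx1 was at 44.3 ± 1.08 and 51.7 ± 1.76, with 20 of 26 sites ranked higher in WT, and Ets1 at 52.9 ± 0.466 and 57.0 ± 0.480. Toward KO, Ypel2 had the largest median shift (48.4 ± 0.945 in KO and 39.7 ± 4.50 in WT), followed by Palld (45.0 ± 2.64 and 34.3 ± 1.63), Dusp22 (52.8 ± 4.22 and 41.6 ± 0.669) and the retinoic acid receptor gene Rarb (43.3 ± 0.228 and 35.4 ± 2.78). Prdm16, which also had 2 KO-only sites, ranked higher in KO at all 13 of its sites (46.5 ± 2.93 in KO and 35.7 ± 1.54 in WT).

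By list, the same ranks were higher in WT for the ETS family (48.2 ± 0.331 against 45.2 ± 0.411, 118 of 182 sites), lymphoid genes (52.9 ± 1.01 against 49.6 ± 0.274, 79 of 112), the cell cycle (56.2 ± 1.01 against 53.5 ± 0.580, 66 of 107), neutrophil genes (50.5 ± 1.08 against 47.9 ± 1.64, 17 of 33) and monocyte genes (52.4 ± 0.445 against 50.1 ± 1.53, 55 of 99). Each of these had groups that did not overlap (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.25 over 15 lists). The housekeeping list did as well, by a smaller amount (61.6 ± 0.178 against 60.9 ± 0.385, exact permutation p = 0.1). These differences were not placed among matched random lists. Genes without overlap leaned toward WT in general (252 against 89), so the values do not show a shift particular to these lists. Another split came close for neutrophil genes (2.22 against 2.64 for KO against WT), monocyte genes (2.28 against 2.32) and housekeeping genes (0.584 against 0.691). The highest other split was further off for the ETS family (1.58 against 3.02), lymphoid genes (1.97 against 3.38) and the cell cycle (1.77 against 2.72). Stem cell regulators as a whole were at 43.8 ± 0.210 in WT and 43.4 ± 0.834 in KO (exact permutation p = 0.5), with Etv6 and Runx1 higher in WT and Prdm16 higher in KO. Other genes of this list, also chosen after their values were seen, had groups without overlap in both directions. Mecom (38.85 in KO and 34.02 in WT), Kit (43.04 and 38.24), Pbx1 (34.55 and 30.27) and Mllt3 (31.8 and 28.01) ranked higher in KO. Erg ranked higher in WT (37.22 in KO and 39.7 in WT). Endothelial genes were at 44.5 ± 0.907 and 43.3 ± 1.54 (exact permutation p = 0.3). With each gene of a list left out in turn, the smallest difference was 1.82 for the ETS family (without Etv6, against 3.02 with it), 1.73 for the cell cycle (without Cdk6, against 2.72) and 2.99 for lymphoid genes (without Tcf7, against 3.38), each still without overlap. Neutrophil, monocyte and housekeeping lists came to overlap without 1 gene (Csf3r, Cx3cr1 and Hprt), and the stem cell regulators without Etv6 stood at -0.837.

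For the group-specific sites, 4 of the 10 splits of whole lists gave as many as KO against WT, which gave 1651 against 2583 for the highest other, and in equal-length lists 1 of 10 did, the real one, with 2373 against 633. With 10 splits no share can fall under 0.05. The 3 other splits that exceeded the real one in whole lists each put KO 3 and WT 1, the shallowest, on one side, and 0 other splits reached the real count at equal length, which is what unequal depth predicts for those splits. DNA of another strain around the targeted locus was tested by the share of group-specific sites within 10 Mb of Fli1, which was 0.848 of that of other sites in exactly 3 libraries (95% interval 0.362 to 1.99), too few sites to decide. For gene lists past the threshold, all 10 splits of whole lists reach the real count of 0 (highest other 0), which decides nothing, and at equal length the real split gave 0 and another, KO 1, KO 2 and WT 3 against the rest, gave 1 (the ETS family, Fisher's exact test, adjusted p = 0.0449).

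WT-only sites gathered at Cdk6 and Etv6, where they made up 70% and 30% of sites in exactly 3 libraries, against 9.88% over all genes. The adjusted p was 0.0587 (Cdk6) and 1 (Etv6) by Fisher's exact test, which by the reading fixed beforehand speaks for long loci with many sites; that reading was changed after the values were seen, because a missed threshold does not show that the shares agree, and long loci stay open for both genes. Sites found in all 6 libraries shifted as well: 12 of 15 ranked higher in WT at Cdk6 and 30 of 35 at Etv6, with median shifts of 7.44 and 7.89 percentage points at the 96.9th and 98.8th percentile of genes with similar numbers of sites. Extra copies of a region reaching far beyond the gene argue for a shift of the neighbourhood too. The median shift of sites within 2 Mb of each gene was only 0.0560 (Etv6) and -0.197 (Cdk6) of the gene's own, which speaks against copies of that extent. Copies of little more than the gene itself would leave that median unchanged, so they stay open. A hypothesis, found and examined on the same 6 libraries, is that Fli-1 loss lowers accessibility across these loci as units; read counts over both loci in further animals of each genotype would test it.

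The excess of WT-only sites at lymphoid genes was seen at equal length (odds ratio 14.9, 0.5 added to each count, Fisher's exact p = 0.00479), so that value alone does not test unequal depth as its cause. At equal length a KO peak below the cut counts as absent. In the 4 deeper libraries shortened to 109250 regions each, where KO-only sites outnumbered WT-only sites in total (4108 and 3462), lymphoid genes had 15 WT-only and 2 KO-only sites (odds ratio 7.11, 95% interval 1.87 to 27.1 for counting error only, Fisher's exact p = 0.000820, adjusted p = 0.00410), which argues against unequal depth as the whole cause. In this setting the excess was not particular to lymphoid genes, since the cell cycle list passed as well. Without Cdk6 that list kept 9 and 2 sites (Fisher's exact p = 0.0300, not adjusted). Before shortening it had 6 and 5 without Cdk6 (Fisher's exact p = 0.367), so its excess beyond Cdk6 rests on the shortened lists. At one length the ETS and stem cell lists also passed, but through Etv6, which both hold. Without it they had 11 and 7 and 13 and 16 sites (Fisher's exact p = 0.244 and 0.855). The 30000 top peaks gave 4 and 1 sites (odds ratio 2.03, Fisher's exact p = 0.654), too few to decide. Among sites found in every library, KO against WT gave 15752 with ranks that did not overlap (27.7%, where chance gives 10%) and the highest of the other 9 splits 5911, so 1 of 10 splits, the real one, reached that number, and a share under 0.05 is out of reach. A different mix of lymphoid-primed progenitors among the LSK cells of the 2 genotypes and a loss of accessibility within each cell were not tested and may both be at work.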
